A study of Bos taurus with 12 samples.

How the data were processed

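Bovine aortic endothelial cells, isolated from aorta and used at passage 15, were grown on glass coverslips for 5 days at confluence in DMEM with 10% fetal bovine serum and 1% antibiotics, per the labels. For 24 h before flow they were kept in medium with 5% serum, 1% antibiotics and 8% Dextran 70. They were then exposed to flow for 24 h in a flow loop with a negative or a positive gradient of wall shear stress (WSS), a uniform baseline of 3.5 Pa or a uniform high level of 28.4 Pa. Each of the 4 groups has 3 arrays, numbered 1 to 3 in the sample titles. Total RNA (RNeasy) was labelled with biotin and hybridized to the Affymetrix bovine array, per the labels. The sources used here do not state whether replicates were separate cultures, on which days the flow runs and hybridizations were done, or the local stress in the gradient chambers. The sample records of the gradient arrays and of the uniform-flow arrays carry separate runs of numbers. Every comparison of a gradient with a uniform flow is therefore also one between these sets of records. Whether the sets were processed apart is not stated.

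The deposited matrix holds log2 values that the authors computed with RMA (background correction, quantile normalization and summary per probe set), and limma is also named, per the submitters' processing notes. Their versions, and settings beyond these names, are not given in the sources used here. The matrix has 24128 probe sets, with values from 1.65 to 14.0. The deposited series matrix repeats 7194 of them, also in log2 units, with 0 cells that differ; no rule for its choice is stated, the largest SD over the 12 arrays outside it was 0.753, and 284 of its probe sets exceeded that. All values used here come from the full matrix, without further scaling. Array medians lay between 5.65 and 5.72. The 112 control probe sets were left out of the tests, so 24016 probe sets were tested. The deposited annotation lists 4770 probe sets, 4743 with 1 symbol and 27 with several. Of the tested ones 4726 had 1 symbol, for 3977 genes. All 4726 Entrez numbers matched the reference annotation (ARS-UCD2.0) and 0 symbols were changed by it. The 19290 others were tested without a name. Where a gene had several probe sets the one with the highest mean over the 12 arrays stood for it.

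All 12 arrays were fitted in 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, eBayes with its default settings), with 8 residual and 4.95 prior degrees of freedom. The 6 comparisons were positive against negative gradient, each gradient and high WSS against baseline, and each gradient against high WSS. Every p-value of a gene or probe set comes from limma. It was adjusted by the Benjamini-Hochberg method over the 24016 probe sets of a comparison, and a probe set was called at an adjusted p under 0.05. A log2 change is the difference of group means, and SE is limma's moderated standard error. Baseline arrays entered 3 comparisons; the calls shared by 2 of them were set against independent lists and against 100 simulations of unchanged groups. Each simulation drew all 12 arrays, baseline included, as independent noise with the SD of each probe set, so it holds the common baseline but neither an effect of the replicate number nor correlation between genes. A probe set counted against both uniform flows when called with 1 sign against each.

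The 29 gene lists, with 685 genes of which 375 were measured, were written from general knowledge. They cover KLF2 and laminar-flow response, vasoactive mediators, NF-kB and leukocyte adhesion, G1/S and DNA replication, G2/M and mitosis, cell cycle inhibitors and p53 targets, apoptosis, matrix proteases and inhibitors, extracellular matrix, contractile and SRF target genes, YAP/TAZ targets, TGF-beta and BMP signalling, Notch and arterial identity, angiogenesis, and junctions and adhesion. The others are NRF2 and oxidative stress, unfolded protein and ATF4 response, heat shock, cholesterol synthesis and uptake, hypoxia and glycolysis, interferon response, immediate early genes, mechanosensing and ion channels, ribosomal proteins, oxidative phosphorylation, and markers of endothelium, smooth muscle and pericytes, fibroblasts and leukocytes. Each list was tested against the other named genes with camera from limma at its preset correlation of 0.01, and its p-values were adjusted over the 29 lists of a comparison. Member p-values were also adjusted over the list alone.

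The groups, comparisons, gene lists, main model, most of the alternatives and the rule for named genes were chosen before the data were examined. Named genes were called genes whose 3 arrays of 1 group all lay above the 3 of the other, a split that chance gives to 10% of unchanged genes. Up to 10 with the largest change at each end were named for positive against negative gradient and up to 6 elsewhere; where nothing was called, the 5 probe sets with the smallest p. Each list named up to 4 called members with the largest change or, with none, up to 2 with the smallest p, as values. KLF2, KLF4, NOS3, THBD, EDN1, VCAM1 and CCL2 were to be named always. Some of the list members named by this rule were left out of the text for length.

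Whether the title numbers pair the arrays was checked by correlating deviations from group means across probe sets. All 12 arrays correlated best with an array of their own number, and 17 of the 18 same-numbered pairs exceeded 0.1 (r from −0.08 to 0.62). The pair below it, between negative gradient and high WSS, is the reason that the fit with the number as a block, with 6 residual degrees of freedom, is given in the report beside the results of the other 5 comparisons. For negative gradient against high WSS it enters only the count against both uniform flows and the closing section. Single values such as control differences were compared by two-sided exact permutation tests.

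The model was tested on simulated data with the variances of the arrays, drawn independently between genes and without an effect of the replicate number, in 5 runs with 200 changed probe sets each. It called 24.5% of 1.5-fold, 71.9% of 2-fold and 96.1% of 4-fold changes, and 4.90% of its calls were unchanged probe sets. A list of 24 genes moved by 0.5 (log2) was called in 20 of 20 runs, and other lists in 0 of 560 tests.

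The alternatives tried were the replicate block, array weights, eBayes with trend and robust options, only the groups compared, each array left out in turn, arrays centred on their medians, quantile normalization once more, and no dim probe sets (the 12008 with the lowest means). Calls were also required to change at least 1.5-fold, or taken from the probe sets of the series matrix or from 1 probe set per gene; lists were tested with an estimated correlation between genes and with fry. Raw CEL files were not analysed here, nor the sources of the unnamed probe sets. Figures were drawn with matplotlib.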

Results

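Gene expression was measured in cultured bovine aortic endothelial cells, the cells that line the aorta and sense the drag of flowing blood as wall shear stress (WSS). The cells were at passage 15 and were kept under flow for 24 h, in 4 conditions with 3 arrays each. Uniform stress was applied at a baseline of 3.5 Pa or at a high level of 28.4 Pa. The other two conditions imposed a spatial gradient of stress, positive or negative along the flow. The labels do not give the local stress in the gradient chambers. Gradient and uniform-flow samples carry separate runs of record numbers, so a comparison between them is also one between these sets. The array tested 24016 probe sets besides its controls, of which 4726 carried 1 gene symbol and together covered 3977 genes. The median log2 signal of the arrays lay between 5.65 and 5.72, and the number of arrays limits the precision. The replicates are not stated to be separate cultures, so every p-value measures only the spread between these samples.

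The 13 measured markers of endothelium ranged from dim to bright in the mean of all arrays. PECAM1, a junctional adhesion molecule of endothelium, averaged 12.0 on the log2 scale over the 12 arrays, at percentile 96.3 of the named genes. CDH5, the endothelial cadherin, averaged 11.1, and TEK, the angiopoietin receptor, averaged 11.5. EGFL7, a secreted protein of endothelium, and ROBO4, an endothelial guidance receptor, lay at percentiles 62.3 and 62.9. FLT1, a receptor of vascular growth factor, averaged 6.90 (percentile 14.8) and PLVAP, the diaphragm protein of fenestrae, 7.46 (24.8). CD14, a monocyte receptor and the only measured member of the leukocyte list, averaged 5.44, at percentile 2.09, with group means of 6.41 at baseline, 5.84 under the negative gradient, 4.88 at high stress and 4.64 under the positive gradient. Of the 2 measured smooth muscle markers, SMTN, which encodes smoothelin, averaged 5.87 (percentile 4.20). TAGLN, an actin-binding protein of contractile cells, averaged 8.95 (percentile 58.4), with group means of 9.95 under the negative gradient, 9.04 at baseline, 8.61 under the positive gradient and 8.19 at high stress. COL1A2, a collagen chain and one of the 5 measured fibroblast markers, averaged 11.9 (percentile 96.1), while THY1, a fibroblast surface protein, averaged 6.71 (percentile 11.6).

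Control probe sets at both ends of a transcript, which report how far RNA and its labelled copies extend, differed between sets of arrays. For EF1A, the elongation factor control, the 3′ minus 5′ difference was −1.23 ± 0.19 (log2, mean ± SD, n = 3) at baseline, −1.42 ± 0.53 at high stress, −1.77 ± 0.28 under the positive gradient and −1.98 ± 0.17 under the negative gradient. Either gradient against baseline gave a two-sided exact permutation p of 0.1, the smallest that 3 arrays against 3 allow. For GAPDH the 6 gradient arrays lay between 0.040 and 0.34 and 5 of the uniform-flow arrays between 0.59 and 0.70, whereas for the ACTB control these ranges overlapped (0.63 to 1.53 and 1.01 to 1.69). High WSS replicate 3, at −2.03 for EF1A and 0.089 for GAPDH, lay in the range of the gradient arrays. This array was also nearest of all to positive gradient replicate 3 (root mean square difference 0.197, the smallest of the 66 array pairs), and lay 0.442 and 0.441 from the other two high WSS arrays.

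**Figure D1:**
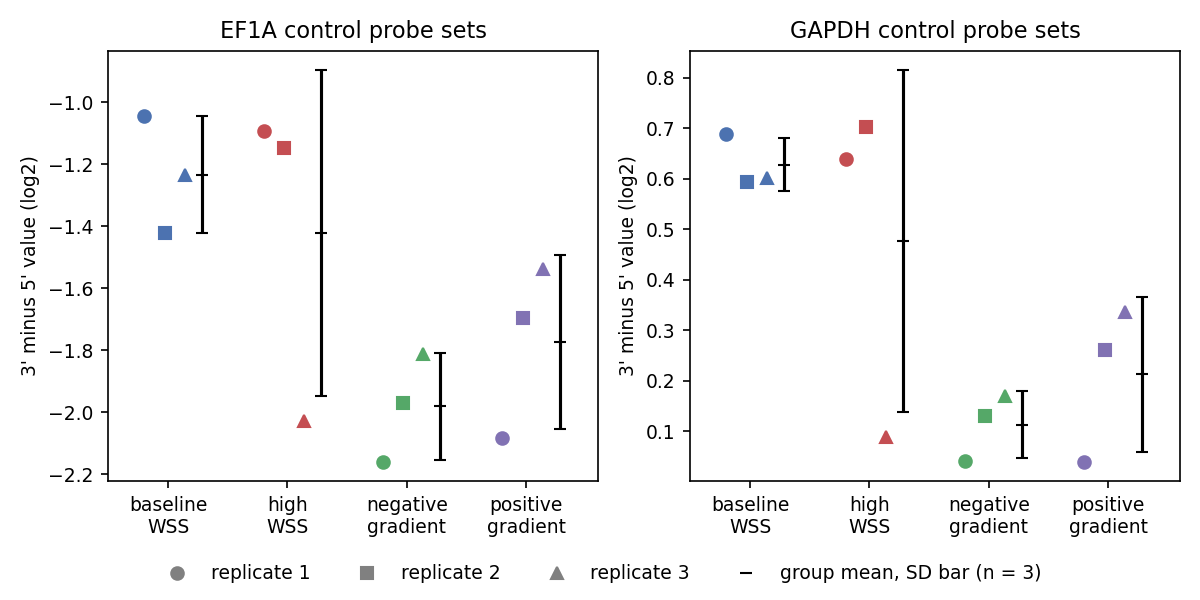
Difference between 3′ and 5′ control probe sets (log2, vertical axis) for EF1A and GAPDH on each of the 12 arrays by flow group, with marker shape for replicate number and bars for group mean and SD (n = 3). The gradient arrays lie between −2.16 and −1.54 for EF1A, and high WSS replicate 3 (−2.03) lies among them.

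The series title names the comparison of the positive with the negative gradient, which asks whether the direction of the gradient matters to endothelial gene expression. Genes of cell division stood higher as groups under the positive gradient. In the list for G1/S and DNA replication all 24 measured members had higher values (median log2 difference 0.47, adjusted p = 1.86e-06 by camera, limma's gene set test, and 0.789 with an estimated correlation between genes). In the list for G2/M and mitosis all 26 did (median 0.62, adjusted p = 6.5e-06, and 0.791 with an estimated correlation). In the pairs numbered 1, 2 and 3 the list means differed by 0.071, 0.75 and 0.64 for G1/S and by 0.28, 0.68 and 0.85 for G2/M. Over the replicate numbers these means ranged by 0.75 and 1.23, more than over the 4 groups (0.69 and 1.10). Neither list had a member past the test, over all probe sets or adjusted over the list alone. Among the values were CCNE2, a cyclin of S-phase entry, at 0.78 (SE 0.304), RFC4, a subunit of the clamp loader of DNA replication, at 0.82 (SE 0.329), ECT2, an exchange factor for cytokinesis, at 0.74 (SE 0.244), and CKS2, a small subunit of cyclin-dependent kinases, at 0.63 (SE 0.302).

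Chaperones of the heat shock list were higher as a group, with all 11 measured members at higher values (median 0.21, adjusted p = 6.4e-05, and 0.497 with an estimated correlation) and 1 higher when adjusted over the list alone. DNAJB1, a co-chaperone of the large heat shock proteins, stood at 0.65 and HSPE1, the mitochondrial co-chaperonin, at 0.43. The oxidative phosphorylation list was higher in 20 of 23 members (adjusted p = 0.00128, and 0.791 with an estimated correlation), among them UQCRB of complex III at 0.36 and COX7C of complex IV at 0.29. Its mean differed by −0.023, 0.20 and 0.30 in the pairs numbered 1, 2 and 3. Cholesterol synthesis and uptake was higher in 14 of 15 (adjusted p = 0.00691, and 0.791 with an estimated correlation), with INSIG1, the sterol-sensing anchor in the endoplasmic reticulum, at 0.56, and DHCR7, the last enzyme of cholesterol synthesis, at 0.29. The extracellular matrix list was lower in 22 of 24 members (median −0.38, adjusted p = 6.5e-06, and 0.497 with an estimated correlation), 9 of them lower when adjusted over the list alone. COL12A1, a fibril-associated collagen, was at −0.93 and THBS2, a matricellular thrombospondin, at −0.82. The mean of the 2 smooth muscle markers differed by −0.67, −0.41 and −0.61 in the pairs numbered 1, 2 and 3, with TAGLN at −1.34 and SMTN at 0.22, and this list was not called (adjusted p = 0.485). The cholesterol list lost its call without negative gradient replicate 1 (adjusted p = 0.224), negative gradient replicate 3 (0.0707) or positive gradient replicate 2 (0.224).

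No gene passed the test alone. By limma, 0 of 24016 probe sets had an adjusted p under 0.05, in the full fit and without any 1 array, and 1247 had an unadjusted p under 0.05. Data were also simulated for this comparison, with 200 changed probe sets in each run. There the same fit called 24.5% of 1.5-fold, 71.9% of 2-fold and 96.1% of 4-fold changes. Where fewer probe sets change the adjusted threshold is stricter, so these shares do not carry over to a comparison with 0 calls. The 3 named genes among the 5 smallest p-values were all lower under the positive gradient, each at an adjusted p of 0.552. They were H4C2, a core histone (5.38 ± 0.40 against 6.50 ± 0.20, SD, n = 3, difference −1.13, SE 0.201), BMP4, a bone morphogenetic protein (5.98 ± 0.39 against 7.36 ± 0.44, difference −1.38, SE 0.261), and FABP5, a fatty acid carrier (9.35 ± 0.40 against 10.6 ± 0.27, difference −1.28, SE 0.245). The other two probe sets had no gene name and stood at 0.85 and 0.77.

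With the replicate number as a block, 6 probe sets were called, 3 higher and 3 lower. The 4 named ones, singled out after their values were seen, were NCEH1, a cholesterol ester hydrolase (1.38, adjusted p = 0.0437 with the block), CCL2, the monocyte chemoattractant (−1.50, 0.0361), PDLIM4, a protein of the actin cytoskeleton (−1.26, 0.0361), and RPRM, a p53-induced cell cycle inhibitor (−1.30, 0.0437). The block added 3 lists, all lower under the positive gradient. For NF-kB and leukocyte adhesion 19 of 20 members had lower values (median −0.69; adjusted p = 2.22e-06 with the block, 0.131 without it, 0.796 with an estimated correlation). Its values included CXCL5, a neutrophil chemokine, at −1.93, CXCL3, a related chemokine, at −0.84, and VCAM1, the vascular adhesion molecule for leukocytes, at −1.44. The leukocyte marker CD14 also had lower values, by −0.29, −1.60 and −1.70 in the pairs numbered 1, 2 and 3 (mean −1.20). The interferon response list (adjusted p = 0.0158 with the block, 0.159 without it, 0.796 with an estimated correlation) included IFI6, an interferon-induced membrane protein, at −1.10. The vasoactive mediators (0.0468 with the block, 0.134 without it, 0.536 with an estimated correlation) included ADM, the vasodilator peptide adrenomedullin, at −0.92.

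Without the block, none of the flow responders reported in every comparison passed between the gradients. NOS3, the endothelial nitric oxide synthase, was at 10.7 ± 0.23 against 10.5 ± 0.56 (difference 0.22, SE 0.372), and KLF4, a flow-induced transcription factor, at 0.62 (SE 0.366). THBD, the anticoagulant thrombomodulin, was at −0.059 (SE 0.156), and EDN1, the vasoconstrictor endothelin, at −0.35 (SE 0.163). Their adjusted p-values were 0.945 or above, and KLF2, which the array's annotation did not name, was not analysed here. NOS3, THBD, VCAM1 and CCL2 changed sign when an array was left out of the fit without the block, which ignores the pairing and leaves a number without its partner, with ranges of −0.0063 to 0.54, −0.11 to 0.0075, −2.93 to 0.14 and −3.07 to 0.12. With the block and all arrays CCL2 stood at −1.50 (SE 0.180, adjusted p = 0.0361) and VCAM1 at −1.44 (SE 0.206, adjusted p = 0.0561). The other 20 lists had adjusted p-values between 0.102 and 0.911 and stayed uncalled with the block. They were the lists of KLF2 and laminar-flow response, p53 targets and cell cycle inhibitors, apoptosis, matrix proteases, contractile and SRF targets, YAP/TAZ targets, TGF-beta and BMP signalling, Notch and arterial identity, angiogenesis, junctions, NRF2 and oxidative stress, unfolded protein and ATF4 response, hypoxia and glycolysis, immediate early genes, mechanosensing, ribosomal proteins, and the endothelial, smooth muscle, fibroblast and leukocyte markers. For p53 targets, YAP/TAZ targets, NRF2 and hypoxia, the median, the mean and the direction of the test did not share 1 sign.

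**Figure D2:**
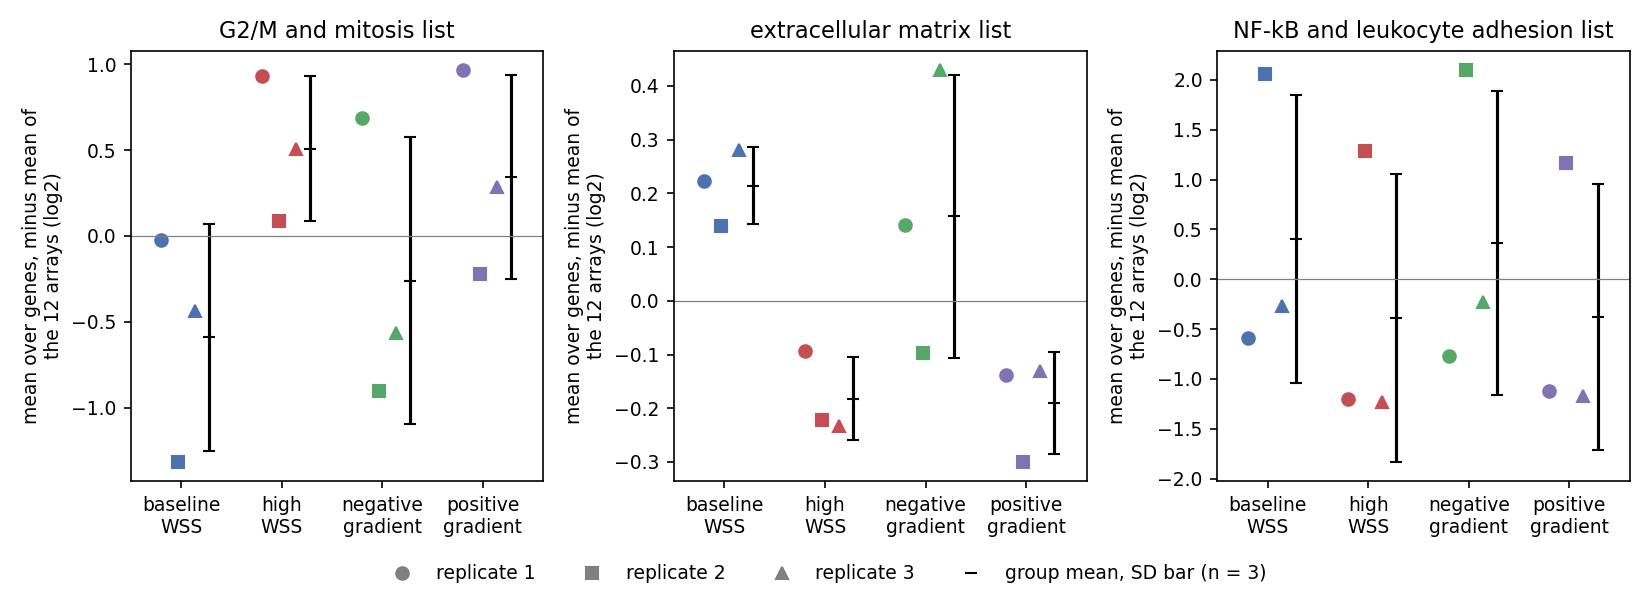
Mean log2 value of the measured genes of 3 lists on each of the 12 arrays, minus the mean of the 12 arrays (vertical axis), by flow group, with marker shape for replicate number and bars for group mean and SD (n = 3). In the NF-kB panel replicate 2 is the highest array of every group (2.10, 1.16, 2.06 and 1.28 for negative gradient, positive gradient, baseline and high WSS).

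The positive gradient was set against baseline to find how cells in such a gradient differ from cells at the low uniform stress. PROCR, the endothelial protein C receptor, rose from 9.06 ± 0.50 to 11.4 ± 0.48 (SD, n = 3; log2 change 2.34, SE 0.478, adjusted p = 0.022). NOS3 rose by 1.72 (SE 0.372, adjusted p = 0.0254). CCND1, the cyclin that carries cells through G1, rose by 2.11 (SE 0.501), PPP5C, a serine/threonine phosphatase, by 1.97 (SE 0.376), and NR4A1, an orphan nuclear receptor of the early response, by 1.78 (SE 0.246). GNAS, a stimulatory G protein subunit, rose by 1.58 at its brighter probe set, while its other probe set stood at −0.29. GAS2, a cytoskeletal protein of growth arrest, fell from 6.89 ± 0.31 to 4.57 ± 0.30 (log2 change −2.32, SE 0.346, adjusted p = 0.0142). Falls were also called for TTR, a carrier of thyroid hormone and retinol (−2.26), FBXO32, a ubiquitin ligase subunit of muscle wasting (−2.08), NR2F1, an orphan nuclear receptor (−1.89), FABP4, a fatty acid carrier (−1.83), and DHRS3, a retinaldehyde reductase (−1.80), at adjusted p-values of 0.0142 to 0.0308.

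**Figure D3:**
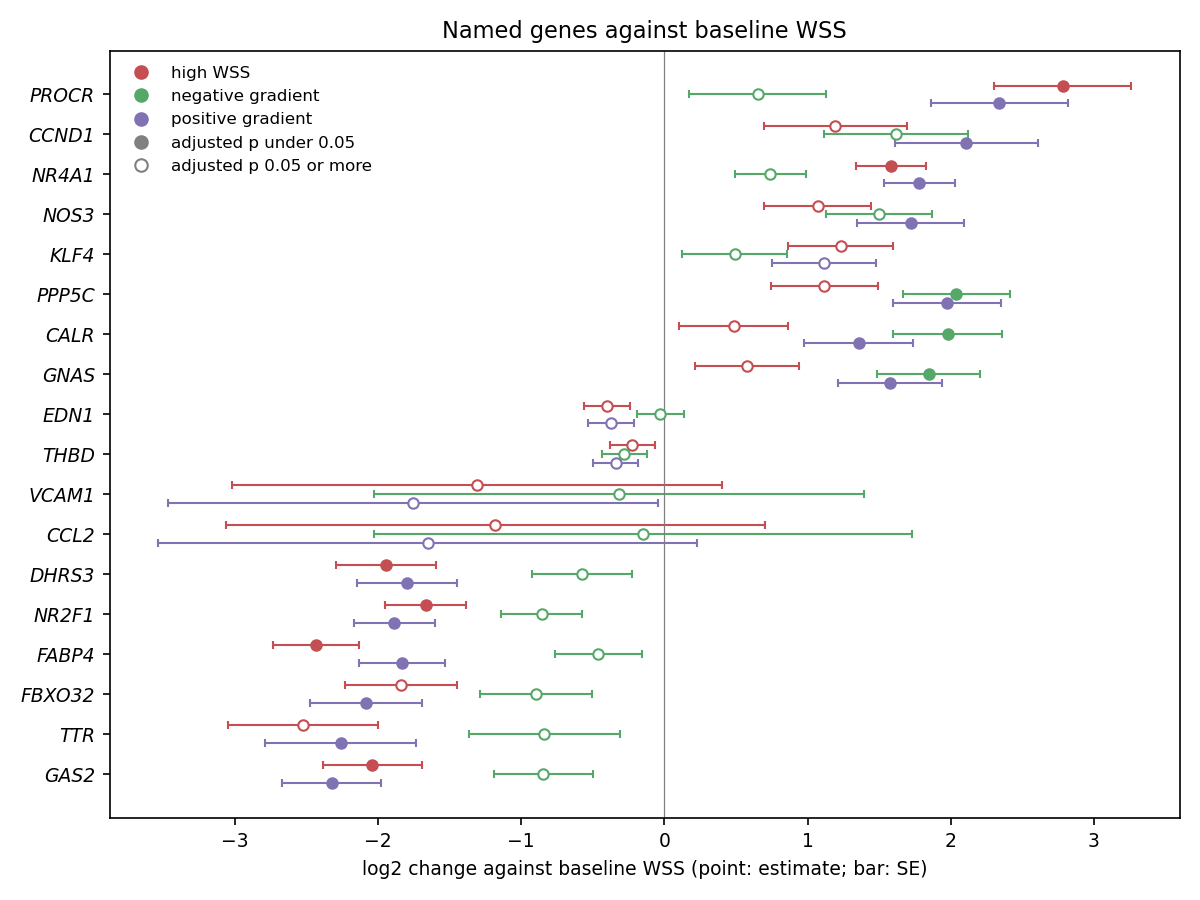
Log2 change of 18 named genes against baseline under high WSS, the negative gradient and the positive gradient (horizontal axis; points are estimates from 3 against 3 arrays, bars are SE, filled points have an adjusted p under 0.05). PROCR reaches 2.78 under high WSS and 2.34 under the positive gradient, FABP4 −2.43 and −1.83.

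Against baseline 6 lists were called. All 24 G1/S genes had higher values (median 0.68, adjusted p = 0.000252, and 0.718 with an estimated correlation) and 1, CCND1, rose, by itself or adjusted over the list alone. All 26 G2/M genes had higher values (median 0.92, adjusted p = 7.81e-05, and 0.718 with an estimated correlation). CKS2 rose (1.08, adjusted p = 0.0496) and none did adjusted over the list alone, whereas 17 G1/S and 24 G2/M genes rose with the block. In the matrix list (adjusted p = 0.00981, and 0.707 with an estimated correlation) 4 members fell, 1 rose and 19 did not pass; 8 fell and 1 rose adjusted over the list alone, and 13 fell and 2 rose with the block. THBS2 (−1.09), FBN1, the microfibril protein fibrillin (−1.08), LAMA4, a laminin chain (−0.71), and COL4A1, a basement membrane collagen (−0.69), fell, though the second probe sets of COL4A1 and LAMA4 stood at 0.21 and 0.36. The mean of the 5 fibroblast markers, 3 of them also in the matrix list, differed by −0.42, −0.39 and −0.64 in the pairs numbered 1, 2 and 3 (adjusted p = 0.427 as a list), and THY1 fell by 1.05 on the log2 scale (adjusted p = 0.0498). In the heat shock list (adjusted p = 0.00127, and 0.636 with an estimated correlation) 5 of 11 rose, 6 adjusted over the list alone, led by CRYAB, a small heat shock protein (1.10), and DNAJB1 (0.85). In oxidative phosphorylation (adjusted p = 0.00355, and 0.718 with an estimated correlation) 4 of 23 rose, also adjusted over the list alone and 6 with the block, among them UQCRC1 of complex III (1.17) and NDUFV1 of complex I (1.14). In cholesterol synthesis (adjusted p = 0.0281, and 0.718 with an estimated correlation) 1 of 15 rose, MVK, mevalonate kinase (0.64); adjusted over the list alone 5 rose, and 6 with the block. The matrix call was lost without positive gradient replicate 2 (adjusted p = 0.0549), and the cholesterol call without positive gradient replicate 2 (0.115) or baseline replicate 1 (0.120).

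The KLF2 and laminar-flow list (adjusted p = 0.0667; 0.0187 with the block; 0.636 with an estimated correlation) had 2 of 13 members higher, NOS3 and PTGIS, the prostacyclin synthase (0.68), with 4 adjusted over the list alone and 6 with the block. KLF4, one of its members, stood at 1.11 (SE 0.366, adjusted p = 0.0785; 0.00572 with the block). The block also called the NF-kB list lower (adjusted p = 0.00736; 0.55 without it, 0.951 with an estimated correlation) with 0 of 20 members past limma's test without it and 8 lower with it. Among these were CSF2, a myeloid growth factor (−2.00, adjusted p = 0.177; 0.00329 with the block), VCAM1 (−1.76, 0.526; 0.00329) and CCL2 (−1.65, 0.591; 0.00329). CD14 of the leukocyte list stood at −1.77. The interferon list was lower with the block (adjusted p = 0.0195; 0.129 without it, 0.729 with an estimated correlation), with 5 of 9 members lower in that fit and 3 adjusted over the list alone without it. IFI6 stood at −1.47 (adjusted p = 0.0543; 0.0098 with the block). THBD (−0.34, adjusted p = 0.176) and EDN1 (−0.37, 0.158) did not pass. The other 20 lists had adjusted p-values between 0.0667 and 0.960.

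Of the 24016 probe sets, 659 rose and 1025 fell by limma (1684 in all), and 4074 were called with the block (1759 higher, 2315 lower). EF1A and GAPDH 3′ minus 5′ differences were lower by 0.54 and 0.41 (log2) in the positive gradient than in the baseline arrays. The count was 0 without positive gradient replicate 2 or 3 (5721 and 5140 at unadjusted p under 0.05), 41 without positive gradient replicate 1, 37, 373 and 1060 without baseline replicates 3, 1 and 2, and 3248 without high WSS replicate 3. None of the 12 named genes stayed past the threshold without each of the 6 arrays in turn.

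The negative gradient was set against baseline to ask the same of a falling stress. CALR, the calcium-binding chaperone of the endoplasmic reticulum, rose from 9.09 ± 0.72 to 11.1 ± 0.32 (SD, n = 3; log2 change 1.98, SE 0.380, adjusted p = 0.0345). PPP5C rose by 2.04, CLN3, a lysosomal membrane protein, by 1.92, HM13, a signal peptide peptidase, by 1.75, and CLK3, a splicing kinase, by 1.73. The probe sets of CALR, CLN3, HM13 and CLK3 carry a second number above 1 in their names, a kind that the closing section takes up. GNAS rose by 1.85 at its brighter probe set, with the other probe set at −0.44. Falls were called for GNB4, a G protein beta subunit (−1.44), BRWD1, a chromatin reader (−1.39), TAOK3, a stress-activated kinase (−1.39), ZNF292, a zinc finger protein (−1.26), APC, the scaffold that limits Wnt signalling (−1.21), and RUFY3, an organelle transport adaptor (−1.15). Adjusted p-values of these 11 genes lay between 0.0284 and 0.0466. The probe sets of GNB4, ZNF292, APC and RUFY3 carry an A before the last number of their names, which the closing section also takes up.

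Within the lists, TIE1, an endothelial receptor kinase, rose by 1.18 and CD34, a sialomucin of endothelium, by 0.72; both belong to the endothelial list, which had 2 of 13 members higher and 4 adjusted over the list alone. UQCRC1 (1.18) and NDUFV1 (1.06) rose among the 23 genes of oxidative phosphorylation. SLC3A2, an amino acid transporter subunit (1.23), rose beside CALR among the 19 genes of the unfolded protein list. ITGA5, the fibronectin receptor subunit (0.71), P2RY2, a nucleotide receptor that endothelium uses in flow sensing (1.05), and SPARC, a matricellular protein (0.83), rose in the lists of junctions, mechanosensing and matrix. All 29 lists had adjusted p-values between 0.103 and 0.970. With the block, G2/M (adjusted p = 0.00228; 0.256 without it, 0.896 with an estimated correlation; 0.71, 0.41 and −0.13 in the pairs numbered 1, 2 and 3), the KLF2 list (0.0482; 0.256; 0.88) and the endothelial list (0.0482; 0.103; 0.88) were called higher. Markers of other cell types were not called as lists, and their means differed in the pairs numbered 1, 2 and 3 by 1.15, 0.52 and 0.46 for smooth muscle, −0.23, −0.46 and −0.19 for fibroblasts (THY1 at −1.24) and −0.68, −0.87 and −0.17 for leukocytes. NOS3 stood at 1.5 (SE 0.372, adjusted p = 0.0588; 0.0252 with the block) and KLF4 at 0.49 (adjusted p = 0.435). THBD (−0.28) and EDN1 (−0.028), VCAM1 (−0.32) and CCL2 (−0.15) did not pass, and without 1 array, in fits that ignore the pairing, EDN1 ranged from −0.093 to 0.10, VCAM1 from −1.89 to 1.05 and CCL2 from −1.77 to 1.40.

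By limma 289 probe sets rose and 112 fell (401 in all), and 1590 were called with the block (917 higher, 673 lower). EF1A and GAPDH 3′ minus 5′ differences were lower by 0.75 and 0.51 in the negative gradient than in the baseline arrays. The count was 0 without any 1 of the negative gradient arrays or baseline replicates 1 and 3 (3789 to 5384 at unadjusted p under 0.05), 109, 115 and 171 without positive gradient replicates 1, 2 and 3, and 2073 without high WSS replicate 3. None of the 12 named genes stayed past the threshold without each of the 6 arrays in turn.

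High uniform stress was set against baseline to show what stress level does without a gradient. PROCR rose from 9.06 ± 0.50 to 11.8 ± 0.57 (SD, n = 3; log2 change 2.78, SE 0.478, adjusted p = 0.029), and FABP4 fell from 9.72 ± 0.20 to 7.28 ± 0.59 (−2.43, SE 0.302, adjusted p = 0.012). NR4A1 (1.58), MALL, a membrane raft protein (1.39), DCK, which phosphorylates deoxynucleosides (1.39), NOCT, a circadian deadenylase-like protein (1.28), and SPRY2, a brake on growth factor signalling (1.21), rose. GAS2 (−2.04), DHRS3 (−1.95), FABP5 (−1.78), NR2F1 (−1.67) and XAF1, an interferon-inducible promoter of apoptosis (−1.55), fell. Adjusted p-values of these 10 lay between 0.012 and 0.0453.

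Cell division genes were again higher as groups. All 26 G2/M genes had higher values (median 1.08, adjusted p = 3.71e-09, and 0.675 with an estimated correlation), 0 past limma's test over all probe sets, 19 adjusted over the list alone and 26 with the block, with CKS2 at 1.09 and ECT2 at 0.92. All 24 G1/S genes did (median 0.76, adjusted p = 3.47e-07, and 0.675 with an estimated correlation), 14 higher with the block and 0 adjusted over the list alone, with CCNE2 at 0.92 and E2F1, a transcription factor of S-phase genes, at 0.74. Heat shock (adjusted p = 3.36e-05, and 0.566 with an estimated correlation; 7 of 11 adjusted over the list alone, 4 with the block), cholesterol (3.66e-05, and 0.675 with an estimated correlation; 8 of 15 and 6) and oxidative phosphorylation (0.00143, and 0.78 with an estimated correlation; 0 of 23 and 1) were higher as groups, with 0 members past limma's test over all probe sets. SQLE, an oxidase of sterol synthesis, stood at 0.75. Matrix was lower (adjusted p = 0.000473, and 0.566 with an estimated correlation), with 9 of 24 lower adjusted over the list alone and 7 lower and 1 higher with the block, FBN1 at −0.96 and THBS2 at −0.92. The mean of the 5 fibroblast markers differed by −0.23, −0.042 and −0.73 in the numbered pairs (adjusted p = 0.508 as a list), with THY1 at −0.46. The oxidative phosphorylation list was no longer called without baseline replicate 2, where its adjusted p rounds to 0.05 from above.

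The interferon list was lower (adjusted p = 0.0446; 0.78 with an estimated correlation), with 2 of 9 lower adjusted over the list alone and 4 with the block; IFI6 stood at −1.45. It lost the call without baseline replicate 2 (adjusted p = 0.351), high WSS replicate 1 (0.142) or high WSS replicate 3 (0.116). The immediate early genes were higher (adjusted p = 0.0477; 0.0526 with the block; 0.566 with an estimated correlation), with NR4A1 risen and, adjusted over the list alone, 5 of 15 higher and 2 lower. That call was lost without baseline replicate 1 (0.162) or 3 (0.101), or high WSS replicate 2 (0.0939) or 3 (0.145). The block called 2 more lists lower, NF-kB (adjusted p = 0.00136; 0.485 without it, 0.867 with an estimated correlation; 7 of 20 lower) and Notch and arterial identity (0.0477; 0.0921; 0.566; 2 of 7 lower). EFNA1, an ephrin ligand, fell by 0.85 on the log2 scale (adjusted p = 0.0332). KLF4 stood at 1.23 (adjusted p = 0.143; 0.00416 with the block) and NOS3 at 1.07 (0.201; 0.0265). CSF2 was at −2.39 (adjusted p = 0.241; 0.00242 with the block), VCAM1 at −1.31 (0.774; 0.00496) and CCL2 at −1.18 (0.821; 0.0043), and CD14 of the leukocyte list at −1.53; without 1 array, in fits that ignore the pairing, VCAM1 ranged from −2.99 to 0.063 and CCL2 from −2.68 to 0.37. THBD (−0.22) and EDN1 (−0.40) did not pass.

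By limma 27 probe sets rose and 71 fell (98 in all), 1294 were called with the block (562 higher, 732 lower), and 0 with only these 2 groups in the fit (2856 at unadjusted p under 0.05). High WSS replicate 3 shared its control differences with the gradient arrays; without it the count was 17, of which 14 were among the 98. It was 38, 46 and 37 without baseline replicates 1, 2 and 3, 23 without high WSS replicate 1 and 63 without positive gradient replicate 3. Of the 12 named genes only FABP4 stayed past the threshold without each of the 6 arrays in turn.

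Responses against the same baseline were then compared with each other. PROCR, NR4A1, GAS2, NR2F1, DHRS3 and FABP4 were called in 1 direction under both the positive gradient and high stress, and PPP5C and GNAS rose under both gradients. The positive and the negative gradient shared 261 calls of the same sign and 0 of opposite sign, where independent lists would share 12.7 and 12 simulated arrays of unchanged groups with a common baseline shared 0. The simulation drew independent noise for every probe set and array, without the effect that arrays of the same number share. With no group changed, almost no probe set is called in it, so a shared count near 0 was set in advance. It does not show how many shared calls a common baseline would add to lists as long as the real ones. Log2 changes correlated at r = 0.84 across probe sets (0.50 simulated; covariance 0.114 against 0.0238 simulated), and probe sets are not independent replicates. The positive gradient and high stress shared 93 calls (3.77 for independent lists, 0 simulated; r = 0.84; covariance 0.103 against 0.0236). The negative gradient and high stress shared 7 (0.656 for independent lists, 0.01 simulated on average; r = 0.58; covariance 0.0625 against 0.0238). With the block these counts were 1120, 1133 and 239, the last beside 2 of opposite sign. Because 3 baseline arrays cannot be split into sets of at least 2, part of each excess may come from the shared controls. The gradient arrays also lay apart from the baseline arrays in the EF1A and GAPDH control probe sets, and high WSS replicate 3 lay among them. A difference in the handling of arrays could thus add shared calls and raise these correlations, which was not tested.

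The shared counts rested on few arrays. The 261 became 0 without any 1 negative gradient array, positive gradient replicate 2 or 3, or baseline replicate 1 or 3, 7 without positive gradient replicate 1 and 1496 without high WSS replicate 3. The 93 became 0 without positive gradient replicate 2 or 3, 27 without positive gradient replicate 1, 34, 43 and 16 without baseline replicates 1, 2 and 3, and 23 and 15 without high WSS replicates 1 and 3. The 7 became 0 without any 1 negative gradient array or baseline replicate 1 or 3, 4 without any 1 positive gradient array, 12 without baseline replicate 2 and 16 without high WSS replicate 2. In the limma fits without 1 array, each comparison against baseline had 2804 or more probe sets at unadjusted p under 0.05, not necessarily the same ones.

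The positive gradient was set against high uniform stress, the second control without a gradient. No gene passed, and no list of division genes did: medians were −0.036 for G1/S and −0.14 for G2/M, where 24 of 26 members had lower values. CCND1 stood at 0.91 (SE 0.501), NOS3 at 0.65 (SE 0.372), SLC3A2 at 0.83 (SE 0.211), TIE1 at 0.65 (SE 0.247), FOS, an immediate early transcription factor, at −0.67 (SE 0.246), each with an adjusted p of 0.79. KLF4 (−0.12), THBD (−0.12), EDN1 (0.027), VCAM1 (−0.45) and CCL2 (−0.47) did not pass either. Without 1 array, in fits that ignore the pairing, KLF4 ranged from −0.31 to 0.035, EDN1 from −0.11 to 0.15, VCAM1 from −1.94 to 1.23 and CCL2 from −2.04 to 1.03. The 5 probe sets with the smallest p were all without a gene name, 2 with higher values (0.86, adjusted p = 0.542, and 0.82) and 3 with lower values (−0.59 to −0.85). None of the 29 lists was called (adjusted p-values 0.230 to 0.979), with the block either. By limma 0 probe sets were called and 1424 had an unadjusted p under 0.05, with 0 called with the block and 1 with array weights. Without high WSS replicate 3, the array nearest of all to positive gradient replicate 3, 342 were called (225 higher, 117 lower). With the block and without that array 1733 were called. The counts of 0 therefore do not show that the positive gradient and high stress are alike.

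The negative gradient was set against high uniform stress for the same reason. FABP4 was higher at 9.25 ± 0.13 against 7.28 ± 0.59 (SD, n = 3; log2 difference 1.97, SE 0.302, adjusted p = 0.0376). FABP5 (1.46), CD93, an endothelial transmembrane receptor of adhesion (1.46), RCN3, a calcium-binding protein of the secretory pathway (1.44), SELENOP, a selenium carrier (1.32), YPEL3, a small growth-suppressing protein (1.08), and PTGDS, a prostaglandin D synthase of the laminar-flow list (0.90), rose. SGPP1, a sphingosine phosphate phosphatase (−1.07), and AMD1, an enzyme of polyamine synthesis (−0.88), fell; adjusted p-values of these 8 lay between 0.0282 and 0.0495.

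All 26 G2/M genes had lower values under the negative gradient than at high stress (median −0.81, adjusted p = 9.58e-05, and 0.559 with an estimated correlation), as did 23 of 24 G1/S genes (adjusted p = 0.00014, and 0.559 with an estimated correlation), with BUB1, a kinase of the mitotic checkpoint, at −1.17 and RRM1, a subunit of ribonucleotide reductase, at −0.62. Each of the 3 list calls that follow also had an adjusted p of 0.559 with an estimated correlation. Heat shock (11 of 11 lower values, adjusted p = 0.00761, 1 lower adjusted over the list alone) and cholesterol (14 of 15, 0.00162) were lower, matrix was higher (21 of 24, 0.0016, 5 adjusted over the list alone), with BGN, the proteoglycan biglycan, at 0.93 and LOXL1, a lysyl oxidase of elastin, at 0.97. The mean of the 2 smooth muscle markers differed by 1.6, 0.70 and 0.33 between arrays numbered 1, 2 and 3, in a list that was not called, with SMTN at −0.013. No member of these 5 lists passed over all probe sets, nor adjusted over the list alone except where stated. The matrix call was lost without negative gradient replicate 3 (adjusted p = 0.126), and those of heat shock (0.0976) and cholesterol (0.0945) without high WSS replicate 3. BMP4 stood at 1.51 (adjusted p = 0.059) and TAGLN at 1.77 (0.0723). KLF4 (−0.74), NOS3 (0.43), EDN1 (0.37), THBD (−0.057), VCAM1 (0.99) and CCL2 (1.03) did not pass. Without 1 array, in fits that ignore the replicate number, THBD ranged from −0.20 to 0.022, VCAM1 from −0.58 to 2.67 and CCL2 from −0.59 to 2.53. The other 24 lists had adjusted p-values between 0.0994 and 0.978. Among them, the mean of the NF-kB list differed by 0.43, 0.81 and 1.00 between arrays numbered 1, 2 and 3. Its test with the block is given in the closing section.

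By limma 15 probe sets rose and 8 fell (23 in all), and 0 were called with only these 2 groups in the fit (2774 at unadjusted p under 0.05). With each array centred on its median the split was 4 higher and 6 lower. The count was 6, 1 and 1 without negative gradient replicates 1, 2 and 3, 1, 0 and 1767 without high WSS replicates 1, 2 and 3 (2600 at unadjusted p under 0.05 for the 0), 3 and 1 without baseline replicates 1 and 3, and 8 without positive gradient replicate 2 or 3. EF1A and GAPDH 3′ minus 5′ differences were lower by 0.56 and 0.36 in the negative gradient than in the high WSS arrays (exact permutation p = 0.3 for each). None of the 8 named genes of the rule stayed past the threshold without each of the 6 arrays in turn.

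A gradient was also set against both uniform flows together, which asks what differs from uniform stress at either level. In the EF1A and GAPDH controls the 6 gradient arrays lay apart from all uniform-flow arrays except high WSS replicate 3. A difference in the handling of the arrays could thus pass both comparisons too, and the design cannot tell it from a gradient. For the negative gradient 8 probe sets passed both comparisons with 1 sign, 6 higher and 2 lower; the count was 0 with only the 3 groups involved, 224 with the block and 587 with array weights. The named ones, singled out after their values were seen, were GPR108, a Golgi membrane protein (0.70 against baseline and 0.93 against high stress), PLPP5, a lipid phosphatase (1.38 and 1.5), and RCN3 at both of its probe sets (1.08 and 1.44; 1.33 and 1.65). The 8 became 0 without any 1 negative gradient array, baseline replicate 1 or 3, or high WSS replicate 1 or 2, 3 without baseline replicate 2 and 904 without high WSS replicate 3. For the positive gradient 0 probe sets passed both by limma, where the comparisons alone had 6683 and 1424 at unadjusted p under 0.05; the count was 0 with the block, 1 with array weights and 265 without high WSS replicate 3.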

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

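The tests of how high WSS replicate 3 and the gradient arrays were processed, and of the probe set names, were chosen after the results were seen; the counts over other splits of the arrays were planned.

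Control probe sets, which none of the comparisons use, differed between groups of arrays. The EF1A 3′ minus 5′ difference relative to baseline was −0.54 (log2) in the positive gradient and −0.75 in the negative gradient, which sets these groups apart. It was −2.03 in high WSS replicate 3, outside the range of the other 5 uniform-flow arrays (−1.42 to −1.04) and inside that of the 6 gradient arrays (−2.16 to −1.54).

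High WSS replicate 3 lay nearest to positive gradient replicate 3 among all arrays. Its EF1A difference of −2.03 is where an array handled together with the gradient arrays would lie. Its largest distance to a positive gradient array was 0.323 (log2), within the 0.342 between positive gradient arrays themselves, so that RNA of a positive gradient culture under a wrong label may also explain it. From the nearer of the number 3 arrays of the negative gradient and baseline it lay 0.364, farther than from positive gradient replicates 1 and 2. These distances include the differences between groups, so they cannot decide on a cause shared by all arrays numbered 3. Its deviations from the group mean correlated with those of number 3 arrays at 0.330 for the positive gradient, 0.149 for baseline and −0.079 for the negative gradient. A biological resemblance of high stress and the positive gradient stays open, untested.

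Both gradients differed from baseline at many probe sets, among them genes such as PPP5C and GNAS that rose in both. High WSS replicate 3 minus the other high WSS arrays correlated at r = 0.697 with negative gradient minus baseline, which shares no array with it. Gradient arrays handled apart from baseline arrays could give this value and may be a part of these differences. A positive gradient culture under a wrong label could give it too. Positive gradient minus high WSS correlated at 0.696 with negative gradient minus baseline. The value therefore cannot tell handling from an effect of the gradients. Of the probe sets higher under the negative gradient 46.7% carried a second number above 1 in their name, which the array uses for further sequences of a transcript cluster, against 18.0% of all (Fisher's exact p = 2.07e-29). That test counts probe sets of the same arrays as independent, so its p does not measure the spread between arrays. The share was 36.1% of those higher under the positive gradient and 3.70% (1 of 27) of those higher at high WSS. Among the named genes, the probe sets of CALR, CLN3, HM13 and CLK3 carry such a number, and those of PPP5C and GNAS do not. Probe position or transcript variants read differently between sets of arrays could give these shares. Of the probe sets lower under the negative gradient, 58.0% carried an A before the last number of their name, against 39.3% of all. Among those lower under the positive gradient this share was 39.3%. The cause of the higher share was not tested. An effect of the gradients that the design names stays open, untested.

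Splits of the 6 arrays of a comparison other than the real one called few probe sets. The 10 splits are too few for a share under 0.05. For the positive gradient against baseline 1 of 10 reached the real 1684 (highest other 0), for the negative gradient against baseline 1 of 10 reached 401 (highest other 0), for high WSS against baseline 1 of 10 reached 98 (highest other 1), and for the negative gradient against high WSS 1 of 10 reached 23 (highest other 0). Where the real count was 0, for the positive gradient against the negative gradient and against high WSS, 10 of 10 reached it. With the block only 4 splits part the pairs, again too few. There 1 of 4 reached the real 6, 4074, 1590 and 1294 for positive against negative gradient and the 3 comparisons with baseline (positive gradient, negative gradient, high WSS), with highest others of 0, 0, 0 and 1, and 4 of 4 reached the real 0 for the positive gradient against high WSS.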

How the results depend on the processing

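The replicate block combined with leaving out high WSS replicate 3, and the block with an estimated correlation between genes, were tests chosen after seeing the data, as was leaving out that array where high WSS was not compared; the others were planned.

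Of 145 alternative counts 69 stayed within 1.5 times, 68 moved and 8 went from 0 to more; of 42 shared counts 10 stayed within that. With the block the counts were 6 for positive against negative gradient, 4074, 1590 and 1294 for positive gradient, negative gradient and high WSS against baseline, 1030 for negative gradient against high WSS and 224 for negative gradient against both uniform flows; shared calls were 1120, 1133 and 239. With the block and without high WSS replicate 3 they were, in the same order, 49, 6181, 4470, 635, 4173 and 2163, with 1733 for positive gradient against high WSS and 1282 for it against both uniform flows. Array weights gave 3977 and 1425 for the gradients against baseline, 1 and 1704 against high WSS, and 1 and 587 against both. With only the groups compared they were 2551 for positive gradient against baseline, and by limma 0 for high WSS against baseline (2856 at unadjusted p under 0.05), 0 for negative gradient against high WSS (2774) and 0 for it against both. The trend and robust options gave 201 for high WSS against baseline, 117 for negative gradient against high WSS and 28 against both; the series matrix probe sets 189, 57 and 18, where fewer were tested; the filter on dim ones 210, 101 and 18, and shared calls of 197 and 11. With 1 probe set per gene, so fewer tested, counts were 799 and 264 for the gradients against baseline, 67 for negative gradient against high WSS and 13 against both. Quantile normalization again gave 15 and 5, and median centring 10 and 3, for negative gradient against high WSS and against both. The cause was not tested elsewhere.

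Without 1 array of the groups compared, or without high WSS replicate 3, the count stayed at 0 between the gradients and ranged from 0 to 3248, 0 to 2073 and 17 to 83 for positive gradient, negative gradient and high WSS against baseline. It ranged from 0 to 342 and 0 to 1767 for the gradients against high WSS, and 0 to 265 and 0 to 904 against both. For the shared calls, without any 1 of the 12 arrays, it ranged from 0 to 1496, 0 to 119 and 0 to 16; the 119 for positive gradient and high WSS came without negative gradient replicate 3. Fewer arrays, and where 2 remain in a group a wider error, are part of each such setting; beyond this the cause was not tested.

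Of 325 alternatives for called lists 233 kept the call and 92 lost it. With an estimated correlation all 25 list calls were lost (adjusted p from 0.497 to 0.791), and with the block as well (0.355 to 0.637), since camera then counts the members of a list as fewer independent genes. By fry, which tests a list without the other genes, 21 were lost, and heat shock and matrix kept the call for positive gradient and high WSS against baseline (adjusted p from 0.0048 to 0.578). Fry also called lists that camera did not. Over all 29 lists it called 7 and 3 in these 2 comparisons, 1 for negative gradient against high WSS and 0 elsewhere. Fry with the block called 14, 12 and 14 there, 3 between the gradients, 4 for negative gradient against baseline and 0 for positive gradient against high WSS. Median centring kept all 25, and the filter on dim probe sets lost the immediate early genes of high WSS against baseline (adjusted p = 0.0623; 1.29e-09 to 0.0623 over both settings and all lists). Besides the lists given in the report, the blocked fit changed no call of a list in the 5 comparisons that the numbers pair; for negative gradient against high WSS it added NF-kB, higher (adjusted p = 0.000462; 0.234 without it, 0.736 with an estimated correlation). What dim signal limits was not separated from the number of tests: without the 12008 dimmest probe sets 98 became 210 for high WSS against baseline and 23 became 101 for the negative gradient against high WSS, but 401 became 296 for the negative gradient against baseline. With all probe sets, the trend and robust options gave 201 and 117 for the former 2.

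Of 5612 values of named genes under alternatives 4431 kept direction and side of the threshold, 571 were weaker, 568 stronger and 42 reversed; none of the values that reversed was called in the fit without a block. With array weights, against baseline, EDN1 (0.026), VCAM1 (0.25) and CCL2 (0.64) reversed for the negative gradient and VCAM1 (0.74), CCL2 (0.56) and CCL5 (0.58) for high WSS. Against high WSS, KLF4 (0.0091) and EDN1 (−0.058) reversed for the positive gradient and VCAM1 (−0.49) for the negative; EDN1 was −0.055 for the positive gradient with the block and without high WSS replicate 3. Without 1 array, in fits without the block, which ignore the pairing, positive against negative gradient ranged from −3.07 to 0.12 for CCL2, −0.0063 to 0.54 for NOS3, −0.11 to 0.0075 for THBD and −2.93 to 0.14 for VCAM1. Against baseline, RSAD2 ranged from −1.46 to 0.33 for the positive gradient; EDN1 from −0.093 to 0.10, VCAM1 from −1.89 to 1.05 and CCL2 from −1.77 to 1.40 for the negative; VCAM1 from −2.99 to 0.063, CCL2 from −2.68 to 0.37 and CCL5 from −2.88 to 0.62 for high WSS. Against high WSS, KLF4 ranged from −0.31 to 0.035, EDN1 from −0.11 to 0.15, VCAM1 from −1.94 to 1.23 and CCL2 from −2.04 to 1.03 for the positive gradient. For the negative gradient THBD ranged from −0.20 to 0.022, VCAM1 from −0.58 to 2.67, CCL2 from −0.59 to 2.53 and CCL5 from −0.19 to 3.08. The ends of the VCAM1, CCL2 and CCL5 ranges came without a replicate 2 array, where the NF-kB list is highest in every group. Such a fit leaves the groups unbalanced over the replicate numbers. For positive against negative gradient with all arrays, the block lowered the SE from 1.71 to 0.206 for VCAM1 and from 1.88 to 0.180 for CCL2. Why the replicate 2 arrays are high was not tested.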

Other observations

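The tests of the resemblance between the differences of the gradients and of stress level were chosen after it was seen; the gene values below come from the planned fit.

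Further single genes were called for the positive gradient against baseline, in lists that were not called. TIMP1, an inhibitor of matrix proteases, rose by 1.25 (log2; SE 0.253, adjusted p = 0.0214), and PLAUR, the urokinase receptor, by 1.22 (adjusted p = 0.0419). TIE1 rose by 1.24 (adjusted p = 0.0211), FLT1, a receptor of vascular growth factor, by 1.19 (0.0394), ITGA5 by 1.04 (0.0135) and P2RY2 by 1.15 (0.0189), while EFNA1 fell by 0.96 on the log2 scale (0.0154). NOX4, a producer of hydrogen peroxide in endothelium, fell by 1.19 (adjusted p = 0.0288), and GCLM, an enzyme of glutathione synthesis, rose by 0.81 (0.0475). ADM, adrenomedullin, fell by 1.47, NPR3, a clearance receptor for natriuretic peptides, fell by 1.66, and NPPC, the C-type natriuretic peptide, rose by 1.13. By camera none of the lists that hold these genes (matrix proteases, angiogenesis, junctions, mechanosensing, NRF2, vasoactive mediators, hypoxia, endothelial markers) was called. The proteases had a median of −0.13 while camera's test pointed up (adjusted p = 0.813). Without positive gradient replicate 2 or 3, 0 probe sets of this comparison were called by limma (5721 and 5140 at unadjusted p under 0.05), these genes included.

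The difference between the gradients correlated across probe sets at 0.607 with that between high and baseline stress, with which it shares no array (0.620 without high WSS replicate 3; Spearman 0.441); FABP5 (−1.28 and −1.78) and BMP4 (−1.38 and −0.86) had 1 sign in both. The correlation was lower, 0.101 to 0.470, in the 9 combinations of single pairs with the same number, and positive gradient minus high WSS against negative gradient minus baseline gave 0.696, so the value alone does not single out stress level; positive gradient minus baseline against negative gradient minus high WSS gave 0.0920. Among 16 combinations of splits that part the pairs 1, the real one, was as large (highest other 0.5), too few for a share under 0.05, so that the resemblance and chance cannot be told apart by them; among all 100 combinations 2 were as large, the other at 0.675. Array processing that set high WSS replicate 3 apart is argued against by a correlation of 0.0627 with the difference between the gradients. A local stress in the gradient chambers that differs between the directions may underlie a part of it, a hypothesis that was not tested, since the labels give no such values.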
